A study of Mus musculus with 8 samples.

How the data were processed

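Heart RNA of aged mice carrying haplotype II of the human angiotensin II type 1 receptor gene was sequenced in 8 libraries, 4 from mice without and 4 from mice with a western diet. Per the labels' protocols, RNA was purified with a Qiagen column kit and libraries were made with an Illumina TruSeq stranded kit after polyadenylated RNA was pulled down. The authors deposited one table of gene-level TPM, with Ensembl gene identifiers as rows and a column for each of the 8 libraries. The submitters' processing notes name kallisto, DESeq2 and the mouse build GRCm38, with no versions or roles; the annotation release and the step from transcripts to genes are not given in the sources used here. TPM divides each transcript's estimated reads by its length and scales the sum of all transcripts to 1000000. The 8 columns summed to between 941318 and 953448, and why they fall short of 1000000 was not tested. Because TPM is relative, a transcript that takes a large share lowers the values of all others, and because it keeps no read depth no counting error, interval or detection limit is given. Values of 0 are described as listed at 0.

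Gene names and coordinates (1-based) were taken from GENCODE vM21 on GRCm38 by Ensembl identifier, which named 29732 of the 30153 identifiers; 421 had no name there and 9045 rows were 0 in all libraries. Among tested genes 36 sets of rows, 72 rows in all, held identical values. Nuclear pseudogenes with at least 90% identity to a mitochondrial transcript over at least 50% of their length were found with megablast (BLAST 2.17.0).

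Groups were taken from GEO's labels. Replicates are numbered in accession order and the numbers pair nothing. Genes with at least 1 TPM in at least 4 of the 8 libraries were tested, 10969 in all, on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model with the group as the only term, empirical Bayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). A count test was not used, since TPM values are not counts. Before the data were examined, 52 gene lists of pathways and cell types, the tests, the alternative settings and the rule for naming genes were fixed. Lists with at least 5 tested members, 42 of the 52, were tested with camera at its preset inter-gene correlation of 0.01, which is more liberal than the correlations estimated here, and adjusted over the 42; camera with an estimated correlation was an alternative. The count of list members past the threshold is given over all genes and adjusted over the list alone. The mitochondrially encoded share of TPM was compared with a two-sided exact permutation test over 70 assignments.

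The rule for naming genes took the 12 genes with the largest rise and the 12 with the largest fall past the threshold whose groups do not overlap, filled up where fewer passed with those of smallest p, which are given as values; always a fixed set that included Agtr1a, Agtr1b, Agt, Ren1, Ace, Nppa, Nppb, Myh7, Col1a1 and Col3a1; and up to 4 members of each list that passed, or up to 3 members past the threshold of other lists. Genes without a symbol, or with a predicted or pseudogene symbol, were counted and not named, and 84 genes met the rule. Outside it are Eif2s3y, Ddx3y, Uty, Kdm5d, Myl7, Irf7, Isg15, Acta2, Npas2, Clock, Cry1 and Nfil3, which belong to fixed lists. The kidney genes Umod, Miox and Slc34a1 are outside it too, and other such genes are marked where they appear.

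The gene and list tests were tested on simulated data with 200 of 10969 genes changed in each of 10 runs. Of changes in TPM + 1, 90.4% of 2-fold and 98.1% of 4-fold ones were recovered, and 5.25% of calls were false. For low genes a 2-fold change in TPM + 1 is more than a 2-fold change in TPM. A list of 25 genes shifted by 0.5 on the log2 scale was found in 10 of 10 runs and an unshifted list in 0. Found here means an unadjusted camera p under 0.05, which is looser than the adjusted p used for the real lists. The simulated genes varied independently of each other. These runs therefore cannot show how often camera with the preset correlation passes unshifted lists whose genes vary together. Genes of the real lists did so, with an estimated correlation of 0.66 for the interferon list.

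The alternative settings chosen beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-of-ratios, quantile and mitochondria-free scaling, other variance priors, library weights, an adjusted p of 0.10, a fold change of at least 1.5, a rank-based camera and leaving out each library in turn. Added after the data were seen were a model term for Y-linked transcripts (Eif2s3y of at least 1 TPM), the 5 libraries with such transcripts alone, the data without the 3 libraries with atrial transcripts (Myl7 of at least 100 TPM), identical rows counted once, removal of mitochondrial genes with their nuclear copies, and fry for the lists. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.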

Results

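The study measured heart RNA of aged mice on a C57/BL6 background that carried haplotype II of the human angiotensin II type 1 receptor gene. This receptor mediates most of the actions of the hormone angiotensin II on blood vessels, heart and kidney. Of the 8 heart libraries, 4 came from mice labelled as aged only, called control here, and 4 from aged mice given a western diet, a feed rich in fat and sugar. The labels give no sex, exact age, length of feeding, collection time or batch. They do not say in so many words that each library is a separate animal, so p-values measure the spread between these 8 samples. Each library listed the abundance of 30153 genes in TPM (transcripts per 1000000 transcripts), and between 10620 and 11175 genes reached 1 TPM. TPM keeps no read depth, so the depth of each library is unknown. Rank correlations across the 10969 genes tested (Spearman, across genes, which are not independent replicates) were 0.972 to 0.986 within groups and 0.966 to 0.980 between groups.

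Several transcripts separated single libraries, partly along the line between the groups. Of the genes given here, only Kap met the rule for naming genes. Eif2s3y, a gene of the Y chromosome, was at 21.1 to 29.0 TPM in the 4 controls and at 22.3 TPM in western diet replicate 4, but at 0 to 0.0231 TPM in western diet replicates 1, 2 and 3. Ddx3y, Uty and Kdm5d, also on the Y chromosome, split the libraries in the same way. Myl7, the atrial myosin light chain, was at 184 TPM in control replicate 1, 1403 TPM in control replicate 3 and 335 TPM in western diet replicate 2, and at 1.10 to 2.87 TPM in the other 5 libraries. Kap, a transcript best known from kidney, was at 7.15 to 72.1 TPM in the western diet libraries and at 0 to 0.685 TPM in the controls. Irf7, an interferon-induced transcription factor, was at 61.0 TPM in western diet replicate 4, at 10.5 to 14.7 TPM in the other western diet libraries and at 3.65 to 5.32 TPM in the controls.

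**Figure D1:**
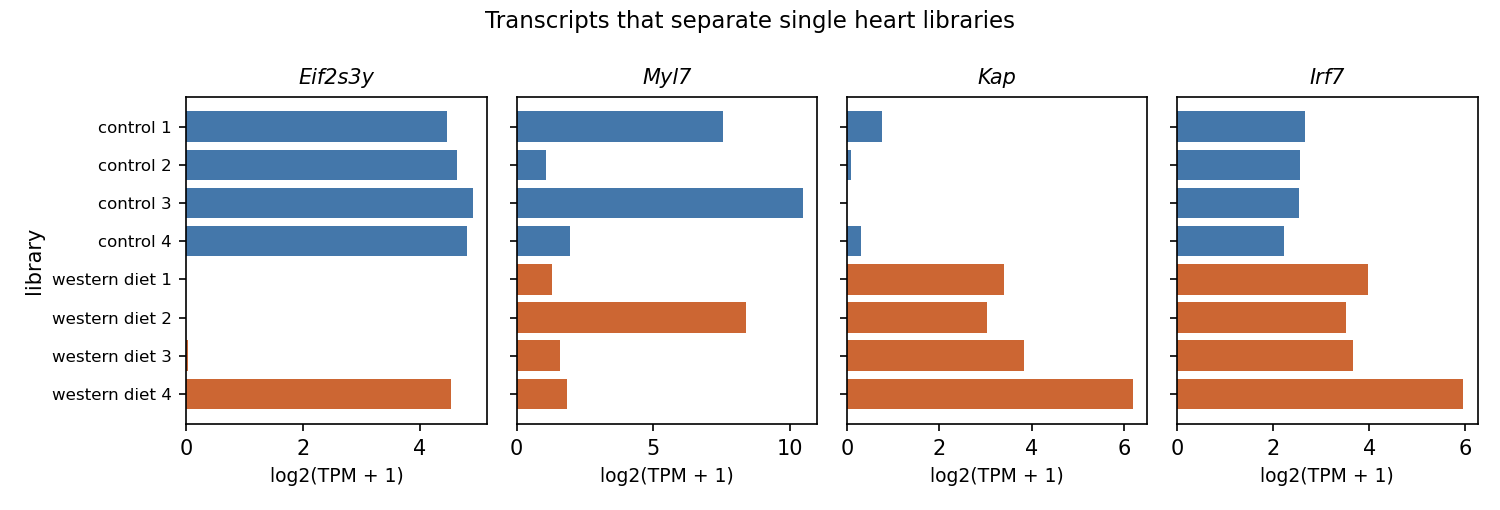
Level of Eif2s3y, Myl7, Kap and Irf7 in each of the 8 heart libraries, as log2(TPM + 1), with control libraries in blue and western diet libraries in orange. Eif2s3y is present in all 4 controls and in western diet replicate 4 alone among the western diet libraries, Myl7 is high in 3 libraries, and Kap and Irf7 are highest in western diet replicate 4.

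The comparison of western diet with control addresses how the diet relates to the heart transcriptome of these aged mice. The western diet hearts held 6.81 times as much Pdk4, the kinase that restrains glucose oxidation by pyruvate dehydrogenase, with 262 ± 88.2 TPM against 38.4 ± 5.24 TPM in control (SD, n = 4 per group; log2 fold change 2.67, SE 0.22, limma adjusted p = 0.000561). Pdk4 (ENSMUSG00000019577) lies on chromosome 6 from 5483351 to 5496309 of GRCm38. The smallest p belonged to Napsa (ENSMUSG00000002204, chromosome 7, 44572380 to 44586862), which encodes the aspartic protease napsin A and was at 3.60 ± 0.389 TPM against 0.332 ± 0.130 TPM (log2 fold change 1.79, SE 0.11, limma adjusted p = 7.43e-05). Cldn5, a tight junction protein of endothelium (chromosome 16, 18776847 to 18778262), doubled from 8.57 ± 0.992 to 17.3 ± 1.38 TPM (log2 fold change 0.94, SE 0.10, limma adjusted p = 0.00527). Among genes past an adjusted p of 0.05, the largest falls in log2(TPM + 1) were those of Penk, the precursor of enkephalin peptides, from 10.3 ± 0.566 to 3.81 ± 1.94 TPM (limma adjusted p = 0.0459), and of Cntn2, a cell adhesion molecule found in the cardiac conduction system, from 2.96 ± 0.434 to 0.661 ± 0.296 TPM (limma adjusted p = 0.00527). Rbm3, a cold-inducible RNA-binding protein encoded on the X chromosome (8138975 to 8145880), fell from 50.01 ± 4.16 to 27.4 ± 2.05 TPM (limma adjusted p = 0.00527).

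In all, 33 of 10969 genes passed an adjusted p of 0.05, of which 25 were higher and 8 lower with western diet. Each of the 33 had its 4 western diet libraries on one side of its 4 controls. Over all genes tested 6.60% did, where chance gives 2.86%. At an unadjusted p under 0.05 there were 1284 genes, against 548 expected by chance. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The other rises with the largest fold changes were those of Kap (25.5 ± 31.1 against 0.249 ± 0.307 TPM), Ucp3, Wdfy1, Oas1a, Oas2, Arntl, Apod, Dynlt1b, Spon2 and Slc25a22. Wdfy1, an adaptor of endosomal Toll-like receptor signalling, was at 4.89 ± 1.49 against 1.16 ± 0.330 TPM. Apod, a lipocalin that binds lipids, was at 13.9 ± 4.71 against 5.63 ± 0.619 TPM, and Slc25a22, a mitochondrial glutamate carrier, at 22.6 ± 5.04 against 10.1 ± 0.855 TPM. Dynlt1b, a dynein light chain that has similar genes beside it on chromosome 17 (reads shared between them were not tested), was at 34.7 ± 6.98 against 15.7 ± 1.15 TPM. Spon2, a secreted matrix protein, was at 4.19 ± 0.768 against 1.52 ± 0.640 TPM. The falls also included the transcription factor Snai3 (1.74 ± 0.437 against 3.96 ± 0.783 TPM). Mlf1, Casq1 and Mkks did not pass: Mlf1 was at 86.5 ± 11.9 against 133 ± 12.1 TPM (limma adjusted p = 0.0514), and the limma adjusted p was 0.0630 for Casq1 and 0.0696 for Mkks.

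Napsa, Pdk4, Rbm3, Cldn5, Cntn2 and Wdfy1 stayed past the threshold whichever library was left out, and the other 27 did not. The count was 15, 9, 13 and 8 without control replicates 1, 2, 3 and 4, and 54 and 95 without western diet replicates 3 and 4. Of the 95, 11 lie on the X or Y chromosome. A model term for the presence of Y-linked transcripts gives a diet estimate that rests on western diet replicate 4. With it 54 genes passed, 11 of them among the 33. All 33 kept their sign, but this lends no support. That library already lies beyond all 4 controls for each of the 33, so the sign was fixed. Of the 6 genes above, Rbm3 (log2 fold change -0.84, SE 0.09, without the term and -0.76, SE 0.14, with it, adjusted p = 0.0537) and Wdfy1 (1.42, SE 0.18, and 0.97, SE 0.23, adjusted p = 0.166) did not pass with this term. Penk went from -1.33 (SE 0.23) to -0.66 (SE 0.27, adjusted p = 0.555). Without the 3 libraries with atrial transcripts 5 genes passed, 3 of them among the 33.

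**Figure D2:**
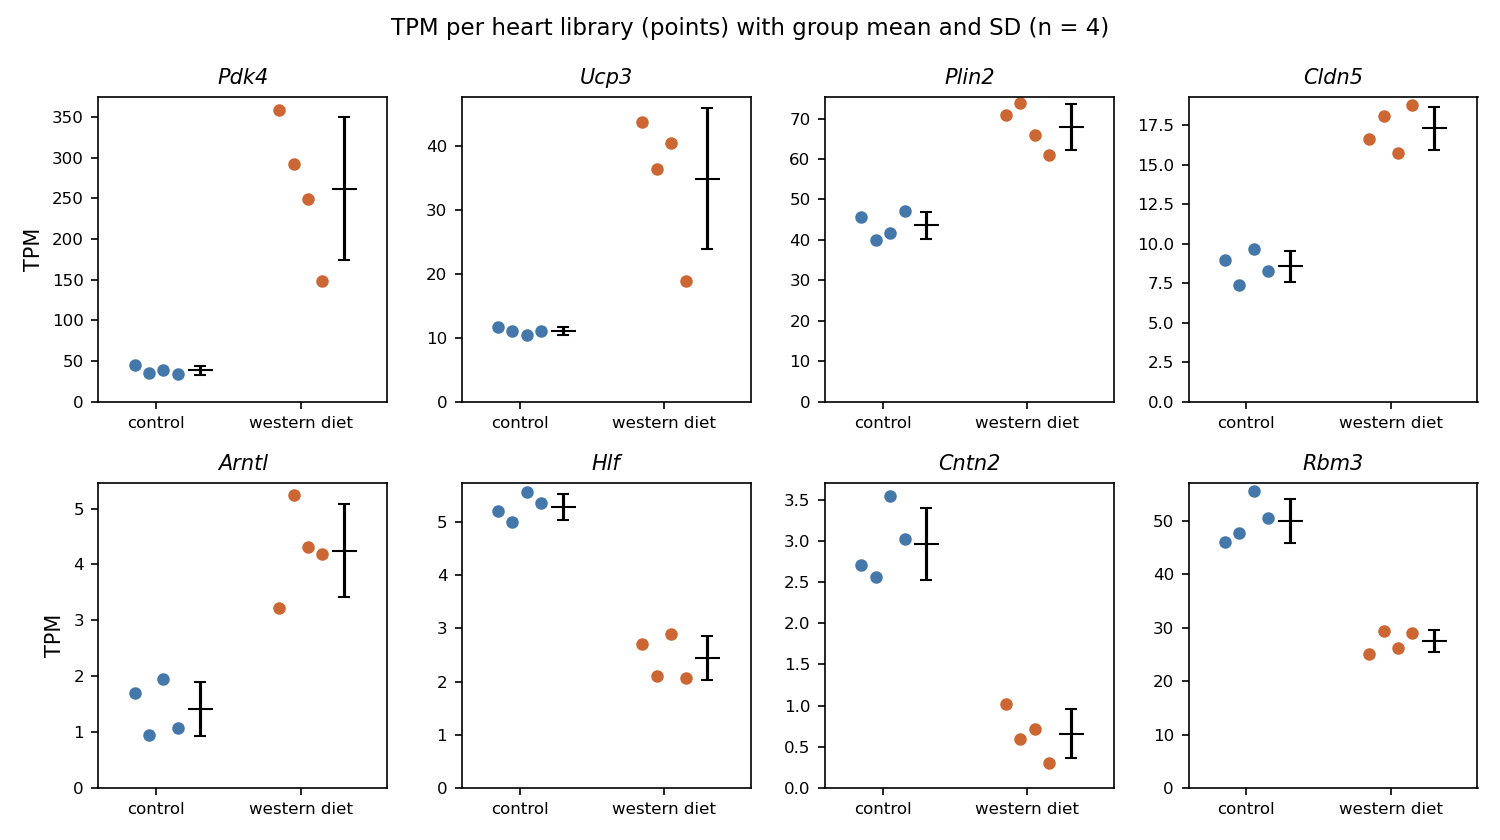
TPM of 8 genes past the threshold in each heart library (points; blue, control; orange, western diet), with the group mean and SD at the right of each group (n = 4). The 4 western diet libraries lie on one side of the 4 controls for each gene, for example at 148 to 359 TPM against 34.2 to 45.4 TPM for Pdk4.

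Genes activated by peroxisome proliferator-activated receptors (PPAR), the fatty-acid-sensing nuclear receptors, rose as a group. All 22 measured members of this list had the higher mean with western diet, with a median log2 fold change of 0.42 (camera adjusted p = 1.47e-14; adjusted p = 0.545 with an estimated correlation). Of the 22, 3 rose past the threshold over all genes and 19 when adjusted over the list alone. Besides Pdk4, these were Ucp3, a mitochondrial uncoupling protein, at 34.9 ± 11.1 against 11.05 ± 0.562 TPM (limma adjusted p = 0.0169), and Plin2, which coats lipid droplets, at 67.9 ± 5.64 against 43.6 ± 3.35 TPM (limma adjusted p = 0.0169). Plin5, another lipid droplet protein, was at 96.3 ± 16.6 against 59.6 ± 5.37 TPM (limma adjusted p = 0.0562). Pdk4 and Ucp3 were lower in western diet replicate 4, the library with Y-linked transcripts, than in the other western diet libraries (148 against 249 to 359 TPM, and 18.9 against 36.4 to 43.7 TPM). With the Y-linked term the log2 fold change of Pdk4 was 1.93 (SE 0.20, adjusted p = 0.00311). That of Ucp3 went from 1.51 (SE 0.21) to 0.73 (SE 0.13, adjusted p = 0.0631), and that of Plin2 from 0.63 (SE 0.09) to 0.48 (SE 0.13, adjusted p = 0.232).

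The list of cholesterol synthesis genes and targets of SREBP2, the sterol-sensing transcription factor, fell slightly, with 14 of 21 members lower and a median log2 fold change of -0.08 (camera adjusted p = 0.000327; adjusted p = 0.545 with an estimated correlation). None of the 21 passed over all genes and 1 did when adjusted over the list alone. Mvd was at 2.58 ± 0.178 against 3.35 ± 0.146 TPM and Idi1 at 1.58 ± 0.236 against 2.20 ± 0.324 TPM. The list of lipogenesis genes and targets of the oxysterol receptor LXR rose, with 15 of 20 members higher and a median of 0.18 (camera adjusted p = 0.0149; adjusted p = 0.820 with an estimated correlation), 0 past the threshold over all genes and 7 adjusted over the list alone. Abca1, a cholesterol exporter, was at 5.05 ± 0.563 against 3.05 ± 0.331 TPM, Lpcat3 at 19.3 ± 2.68 against 13.6 ± 0.682 TPM and Srebf1 at 13.6 ± 3.72 against 8.06 ± 1.56 TPM. Neither list passed with the Y-linked term (adjusted p = 0.139 and 0.205), and the lipogenesis list did not pass without control replicate 4 (adjusted p = 0.0951) or by ranks (adjusted p = 0.0772).

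Transcripts of the circadian clock differed between the groups. Arntl, which encodes the clock activator BMAL1, rose from 1.42 ± 0.483 to 4.24 ± 0.831 TPM (limma adjusted p = 0.0169), while 3 genes of the opposite phase fell: Hlf from 5.28 ± 0.240 to 2.45 ± 0.420 TPM (limma adjusted p = 0.0121), Per3 from 3.33 ± 0.430 to 1.39 ± 0.334 TPM (limma adjusted p = 0.0169) and Tef from 44.7 ± 3.46 to 31.5 ± 1.94 TPM (limma adjusted p = 0.0459). Hlf and Tef are transcription factors of the clock output, and Per3 is a period gene. Of the 18 measured members, 1 rose, 3 fell and 14 did not pass over all genes; adjusted over the list alone 1 rose and 6 fell. Dbp, another output factor, was at 5.57 ± 1.39 against 9.47 ± 1.48 TPM (limma adjusted p = 0.125). The list as a whole tested lower (camera adjusted p = 0.000133, median log2 fold change -0.20; adjusted p = 0.701 with an estimated correlation), but not by ranks (adjusted p = 0.0719). With the Y-linked term Hlf passed (adjusted p = 0.0272), and Arntl, Per3 and Tef did not (adjusted p = 0.166, 0.0859 and 0.391), with larger SEs. The log2 fold change of Arntl was 1.12 without the term (SE 0.16) and 1.12 with it (SE 0.27), that of Per3 -0.86 (SE 0.13) and -1.001 (SE 0.20), and that of Tef -0.49 (SE 0.09) and -0.37 (SE 0.13).

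Interferon-stimulated genes rose as a group. Of 31 members of this list 30 were higher with western diet, with a median log2 fold change of 0.60 (camera adjusted p = 4.50e-15; adjusted p = 0.701 with an estimated correlation). Of these, 2 passed over all genes and 21 adjusted over the list alone. Those 2 encode sensors of double-stranded RNA, Oas2 at 3.77 ± 1.06 against 1.15 ± 0.121 TPM (limma adjusted p = 0.0124) and Oas1a at 4.87 ± 2.21 against 1.44 ± 0.232 TPM (limma adjusted p = 0.0425). Irf9, part of the factor that drives these genes, was at 8.49 ± 1.30 against 5.04 ± 0.388 TPM, and Oasl2 at 10.1 ± 4.92 against 3.69 ± 0.262 TPM. The level was uneven within the western diet group. Isg15, which is outside the rule for naming genes, was at 34.4 TPM in replicate 4 and at 7.88 to 17.7 TPM in the other 3. The list of complement and coagulation genes also rose, with 17 of 22 members higher and a median of 0.31 (camera adjusted p = 0.00319; adjusted p = 0.820 with an estimated correlation), 0 past the threshold over all genes and 3 adjusted over the list alone. Cfb, complement factor B, was at 6.13 ± 1.53 against 2.97 ± 0.498 TPM, and C1qb at 48.2 ± 13.1 against 34.4 ± 3.09 TPM. Plat, a plasminogen activator, was at 11.6 ± 0.791 against 8.16 ± 1.06 TPM. S100a8, a protein abundant in neutrophils, rose from 1.34 ± 0.343 to 3.83 ± 1.19 TPM (limma adjusted p = 0.0319), and was 1 of only 3 neutrophil markers high enough to be tested.

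Matrix genes rose modestly together. Of 33 members of the collagen and matrix list 30 were higher, with a median log2 fold change of 0.24 (camera adjusted p = 1.83e-05; adjusted p = 0.820 with an estimated correlation); none passed over all genes and 11 did adjusted over the list alone. The basement membrane collagens Col4a1 and Col4a2 were at 76.0 ± 9.41 against 56.4 ± 5.18 TPM and 55.7 ± 4.28 against 41.8 ± 4.66 TPM. Thbs1, thrombospondin 1, was at 3.504 ± 1.07 against 1.62 ± 0.620 TPM and Col5a3 at 5.72 ± 1.10 against 3.48 ± 0.721 TPM. Fibroblast markers, 15 of 18 higher with a median of 0.21, rose as a list (camera adjusted p = 0.0177; adjusted p = 0.820 with an estimated correlation), with none past the threshold over all genes and 6 adjusted over the list alone. Among them Col14a1 was at 6.42 ± 2.15 against 2.41 ± 0.630 TPM and Clec3b at 37.9 ± 11.5 against 23.9 ± 2.20 TPM. Col14a1 was at 3.35 TPM in western diet replicate 4, near the highest control, 3.25 TPM. The fibroblast list did not pass with the Y-linked term (adjusted p = 0.0632) or without control replicate 4 (adjusted p = 0.135), or without western diet replicate 1 (adjusted p = 0.0558).

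Smooth muscle and pericyte markers tested lower as a list, with 8 of 13 lower and a median log2 fold change of -0.12 (camera adjusted p = 0.000933; adjusted p = 0.545 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, fell from 18.6 ± 2.22 to 10.003 ± 1.41 TPM (limma adjusted p = 0.0169) and was the 1 member past the threshold over all genes; adjusted over the list alone 4 fell and 1 rose. The member that rose on that scale was Acta2, smooth muscle actin, at 80.8 ± 29.1 against 33.4 ± 5.99 TPM (limma adjusted p = 0.0630 over all genes), so the list did not move one way. Pdgfrb, the pericyte receptor, was at 11.5 ± 0.971 against 14.8 ± 0.886 TPM, Kcnj8 at 4.31 ± 1.20 against 6.51 ± 0.606 TPM and Myh11 at 1.79 ± 0.365 against 3.06 ± 0.812 TPM. With the Y-linked term this list did not pass (adjusted p = 0.750). Endothelial markers did not pass as a list (camera adjusted p = 0.0699), with Cldn5 the 1 of 20 past the threshold.

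Nuclear-encoded genes of oxidative phosphorylation were slightly lower with western diet. Of the 77 members 66 were lower, with a median log2 fold change of -0.09 (camera adjusted p = 1.82e-11; adjusted p = 0.820 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Ndufa5 of complex I was at 726 ± 89.99 against 934 ± 53.8 TPM, Uqcrb of complex III at 730 ± 87.6 against 929 ± 47.0 TPM and Ndufb3 at 195 ± 12.2 against 231 ± 15.1 TPM. Sarcomere genes showed the same direction, with 15 of 23 lower and a median of -0.07 (camera adjusted p = 0.00477; adjusted p = 0.820 with an estimated correlation), and again none past either threshold. Tcap, which caps titin, was at 1379 ± 222 against 1676 ± 130 TPM, and cardiac troponin T, Tnnt2, at 6851 ± 995 against 8020 ± 97.0 TPM. Skeletal muscle markers, 4 of 6 lower with a median of -0.16, tested lower (camera adjusted p = 0.0146; adjusted p = 0.705 with an estimated correlation), 0 past the threshold over all genes and 1, Pvalb, adjusted over the list alone. Pvalb, a calcium buffer, was at 0.252 ± 0.365 against 1.07 ± 0.0402 TPM. This list did not pass without western diet replicate 4 (adjusted p = 0.0849), after median-of-ratios scaling (adjusted p = 0.0651) or by ranks (adjusted p = 0.0719).

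Atrial markers tested lower as a list, 9 of 10 lower with a median log2 fold change of -0.48 (camera adjusted p = 0.00957; adjusted p = 0.820 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Their level followed the 3 libraries with atrial transcripts: Myl4 was at 1023 TPM in control replicate 3, 159 TPM in control replicate 1, 223 TPM in western diet replicate 2 and 2.00 to 4.24 TPM elsewhere. Without these 3 libraries the list turned upward (adjusted p = 0.706), and without control replicate 3 alone its adjusted p was 0.737. It also did not pass without western diet replicate 1 (adjusted p = 0.0720), with the Y-linked term (adjusted p = 0.241) or after median-of-ratios scaling (adjusted p = 0.112). Gja5, an atrial and conduction connexin, was at 2.87 ± 0.873 against 6.20 ± 5.58 TPM, and at 14.5 TPM in control replicate 3. Among cardiac ion channels and gap junction genes, whose list did not pass (camera adjusted p = 0.0560), Scn4b, a beta subunit of the sodium channel, was the 1 of 23 past the threshold, at 31.8 ± 3.24 against 18.3 ± 2.06 TPM (limma adjusted p = 0.0153).

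The immediate early and heat shock lists were higher as groups, with no member past the threshold over all genes. Other stress lists did not pass, such as endoplasmic reticulum stress (camera adjusted p = 0.949) and antioxidant and NRF2 targets (camera adjusted p = 0.179). Immediate early genes, which are induced within minutes of a stimulus, had 20 of 21 members higher and a median log2 fold change of 0.52 (camera adjusted p = 5.13e-05; adjusted p = 0.820 with an estimated correlation), with 0 past the threshold over all genes and 2, Dusp1 and Myc, adjusted over the list alone. Dusp1 was at 11.3 ± 4.30 against 5.90 ± 1.08 TPM and Fos at 3.73 ± 2.05 against 1.602 ± 0.603 TPM. Heat shock genes had 15 of 16 members higher and a median of 0.27 (camera adjusted p = 0.00323; adjusted p = 0.710 with an estimated correlation), 0 past the threshold over all genes and 4 adjusted over the list alone. The small heat shock proteins Hspb8 and Hspb1 were at 363 ± 36.2 against 282 ± 9.78 TPM and 198 ± 32.8 against 146 ± 9.35 TPM.

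**Figure D3:**
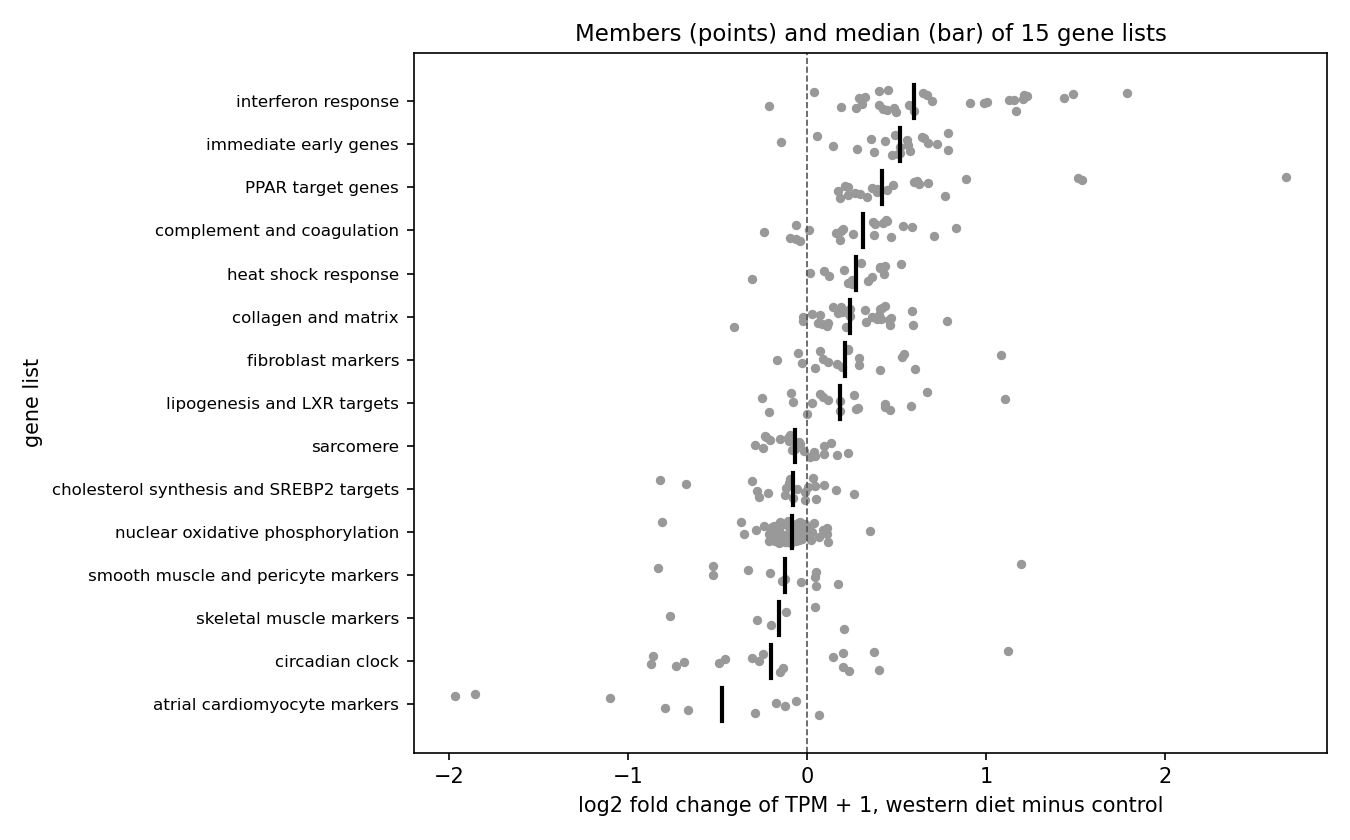
Log2 fold change of TPM + 1, western diet minus control, for each measured member (points) of the 15 gene lists past an adjusted p of 0.05 with the preset correlation, with the list median as a black bar. Medians run from 0.60 for interferon response to -0.48 for atrial markers; none of the 15 lists passed with an estimated correlation.

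Transcripts of the renin-angiotensin system and of cardiac load did not pass over all genes. Agtr1a, the mouse gene for the type 1 angiotensin receptor, was at 15.96 ± 3.43 TPM with western diet and 19.2 ± 2.14 TPM in control (log2 fold change -0.27, SE 0.15, limma adjusted p = 0.511), and Agtr1b was listed at 0 in all 8 libraries. Transcripts of the human receptor transgene were not analysed here. Ace, the angiotensin-converting enzyme, was at 11.2 ± 2.79 against 13.4 ± 1.14 TPM (limma adjusted p = 0.549). Agt and Ren1 were too low to be tested, at means of 1.11 and 0.00724 TPM with western diet and 0.861 and 0.0138 TPM in control. The natriuretic peptide genes were at 327 ± 431 against 1080 ± 1667 TPM for Nppa, which followed the libraries with atrial transcripts, and at 247 ± 177 against 261 ± 25.2 TPM for Nppb. Myh7, the beta myosin heavy chain, was at 67.8 ± 31.4 against 54.3 ± 10.8 TPM (limma adjusted p = 0.772). Col1a1 was at 14.6 ± 2.33 against 10.5 ± 1.54 TPM (limma adjusted p = 0.227) and Col3a1 at 74.6 ± 13.8 against 65.2 ± 11.7 TPM (limma adjusted p = 0.681). The renin-angiotensin and hypertrophy lists did not pass (camera adjusted p = 0.269 and 0.822). Adjusted over the list alone, 0 of 9 renin-angiotensin genes passed and 2 of 17 hypertrophy genes rose, the actins Acta1 (320 ± 132 against 103 ± 24.3 TPM) and Acta2, named here after their values were seen.

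Genes encoded by the mitochondrial genome made up 34.9% ± 5.50 of the listed TPM with western diet and 35.1% ± 0.915 in control (SD, n = 4 per group), a difference within the spread between samples (two-sided exact permutation test, p = 0.943; the smallest possible p is 0.0286). Western diet replicate 1 was lowest at 27.3% and replicate 4 highest at 39.3%. A further 15.8% to 20.9% of TPM per library was listed under 15 nuclear pseudogenes that are near copies of mitochondrial genes, and whether reads were divided between the genes and these copies was not tested. Counted together, the shares were 53.6% ± 5.37 with western diet and 54.2% ± 1.00 in control (exact permutation p = 0.8286).

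Of the 52 gene lists, 42 had at least 5 measured members, and 15 of these passed in camera with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. Among the lists that did not pass, inflammatory cytokines and adhesion (camera adjusted p = 0.0667) had 17 of 22 members higher and fatty acid oxidation (adjusted p = 0.284) 17 of 23. Macrophage markers (adjusted p = 0.545), adipocyte markers (adjusted p = 0.804), erythroid markers (adjusted p = 0.491), TGF beta signalling (adjusted p = 0.518) and endoplasmic reticulum stress (adjusted p = 0.949) did not pass either. The median of all genes was 0.06 on the log2 scale. Camera, which compares a list with the other genes, gave a lower direction for some lists whose own median and mean were above 0 (ribosomal proteins, calcium handling, cell cycle, Schwann and neuronal markers, B and plasma cell markers); none of these passed. For the renin-angiotensin and hypertrophy lists the median was above 0 and the mean below it, and for glycolysis the reverse.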

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

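The tests of a sex difference and of shared handling below were chosen after the results were seen; the count of other splits was planned. In 172 groups of 4 libraries, covering the named genes, Eif2s3y and the mitochondrial share, 15 held a library whose distance from its nearest neighbour took up more of the group's range than Dixon's 95% critical value for 4 samples, which chance gives in about 1 of 20 groups.

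Western diet replicate 4 stood apart from the other 3 western diet libraries in Eif2s3y (22.3 TPM against 0 to 0.0231), Kap (72.1 against 7.15 to 13.4 TPM) and Dynlt1b (24.3 against 37.1 to 39.5 TPM). Control replicate 3 stood apart in Nppa (3562 against 97.4 to 530 TPM), Myl4 (1023 against 2.00 to 159 TPM), Gja5 (14.5 against 2.80 to 3.87 TPM) and Lum (23.7 against 15.1 to 16.3 TPM). Western diet replicate 2 stood apart in Nppa (971 against 69.99 to 171 TPM), Myl4 (223 against 2.65 to 3.65 TPM) and Myl1 (88.1 against 39.7 to 44.1 TPM). Western diet replicate 1 was highest in C1qb (67.8 against 40.2 to 42.6 TPM) and lowest in Pdgfrb (10.1 against 11.9 to 12.1 TPM), and western diet replicate 3 was highest in S100a8 (5.601 against 3.01 to 3.39 TPM). Control replicate 4 was highest in Agtr1a (22.4 against 17.9 to 18.5 TPM) and in the mitochondrial share (36.5% against 34.6% to 34.8%).

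The Y-linked transcripts set 3 western diet libraries apart from all controls, as a difference in sex would, though the labels give no sex. Kdm5c, Eif2s3x, Ddx3x, Kdm6a, Asb11 and Sh3kbp1 on the X chromosome (chosen after their values were seen) were higher in those 3. Their log2 fold changes ran from 0.59 for Kdm6a to 1.04 for Kdm5c. Western diet replicate 4 was not beyond the controls in that direction. Rbm3, also on the X chromosome, was lower in all 4 western diet libraries. The 33 genes past the threshold were therefore weighed against chance, a sex difference and shared handling. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 33 genes or more. The highest of the others gave 2. This argues against chance but cannot exclude it, since 1 of 35 is the smallest share these splits can give. To weigh a sex difference as the whole cause, western diet replicate 4, which has Y-linked transcripts like the controls, was compared with them. It lay beyond all 4 controls in the called direction in 84.1% of the 82 autosomal genes called without it. Exchange with the controls would give 20% for genes not chosen by these controls, and all autosomal genes gave 26.2%. Of the 82 genes, western diet replicate 4 lay within the controls for 10, Zbtb16 included (chosen after its values were seen). It lay beyond the controls on the opposite side for 3, and its median deviation was 0.54 of the change in the other 3 western diet libraries. Of the 11 genes on the X or Y chromosome called without it, it lay beyond the controls in 18.2%. This is 1 library, and the 82 genes were called with the same 4 controls, so exchange may give more than 20% for them. A sex difference and the diet therefore cannot be told apart for these genes. Shared handling of the western diet samples stays open too, since 4 kidney transcripts not looked at beforehand were at 0 in all controls and above 0 in all 4 western diet libraries, 1 of them (Aadat, chosen after its values were seen) at only 6.79e-10 TPM in western diet replicate 3, and the labels give no batch. An effect of the diet on the heart is untested beyond this comparison.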

How the results depend on the processing

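The Y-linked, atrial, identical-row, nuclear-copy and fry alternatives were chosen after seeing the data; the others were planned. The count of 33 genes was 5 without a filter, 15 with a mean of at least 5 TPM, 61 with quantile normalization, 108 with library weights, 95 at an adjusted p of 0.10 and 8 to 95 when 1 library was left out; it was 54 with the Y-linked term, 76 in the 5 libraries with Y-linked transcripts, where western diet replicate 4 is the only western diet library and is assumed to vary like the controls, and 5 without the 3 with atrial transcripts. In the other settings it was 29 to 44. Higher genes made up 75.8% of the calls, and 65.6% after quantile normalization. Over the alternatives this share ran from 55.6% without control replicate 2 (9 calls) to 100% without the 3 atrial libraries (5 calls). All 33 kept their sign in each alternative that tested them. Their groups do not overlap, so only the alternatives that rescale the libraries could have reversed a sign. In the other settings the sign was fixed by the calls and lends no support. The 15 lists became 31 without a filter, and 0 with an estimated correlation, where the 15 had adjusted p of 0.545 to 0.820; fry gave 0 for one direction (lowest adjusted p 0.0867, and 6 lists at an unadjusted p under 0.05) and 10 for either direction. Leaving out 1 library gave 13 to 22 lists. Only the atrial list reversed, without the 3 atrial libraries (adjusted p 0.706). The median of each of the 15 lists kept its sign under median-of-ratios, quantile and mitochondria-free scaling. The difference in the mitochondrially encoded share of TPM, -0.198 percentage points, was 1.87 for medians and ran from -1.65 to 2.36 when 1 library was left out, positive without control replicate 4 (0.258) and western diet replicate 1 (2.36). Among named genes, none past the threshold reversed, with the same limit as for the 33. Over all pairs of such a gene and a setting, the call was kept in 197 and lost in 115. Of the rest, log2 fold changes reversed with the Y-linked term for Ace (0.10), Nppb (0.89) and Myh7 (-0.22), and without the 3 atrial libraries for Myh7 (-0.000714), Myl4 (0.035) and Myl1 (0.17). Leaving out 1 library gave -0.80 to 0.066 for Nppb, reversed without western diet replicate 1, -0.038 to 0.39 for Myh7, reversed without western diet replicate 2, and -0.38 to 0.16 for Myl1, reversed without control replicate 3. Fewer genes or libraries enter the filtered and left-out settings; otherwise the cause was not tested. Tests of single transcripts were not run, since rows are genes. Depth is unknown, so its effect on low genes cannot be given. No paired analysis was possible because the labels give no replicate numbers shared between the groups.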

Other observations

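The tests of the clock, of a general rise of low transcripts and of Napsa below were chosen after the results were seen; the percentage of higher kidney markers was predicted beforehand for markers not yet looked at. The clock grouping, the test of a general rise and the Napsa test were also revised after their values were seen. Genes named in the next paragraph were chosen after their values were seen.

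Some transcripts were uneven within the western diet group. Cdkn1a, the cell cycle inhibitor p21, was at 56.7 and 36.5 TPM in western diet replicates 1 and 2, at 12.5 and 12.5 TPM in replicates 3 and 4, and at 5.63 to 8.12 TPM in the controls (limma adjusted p = 0.116 for the groups). Fkbp5, a gene induced by glucocorticoids, was at 20.2 and 14.4 TPM in western diet replicates 1 and 2 and at 5.88 and 4.59 TPM in replicates 3 and 4, against 3.07 to 4.80 TPM in the controls (limma adjusted p = 0.230). The metallothionein Mt2 was at 76.5 and 42.7 TPM in western diet replicates 1 and 2 and at 11.3 to 18.1 TPM in the other 6 libraries, western diet replicates 3 and 4 included (limma adjusted p = 0.424). Zbtb16, which glucocorticoids also induce, was distributed differently, at 6.38, 9.10, 10.6 and 3.397 TPM in western diet replicates 1 to 4. Hba-a1, a haemoglobin chain of red cells, was at 1912 TPM in western diet replicate 1 and at 243 to 736 TPM in the other 7 libraries. The skeletal actin Acta1 was at 320 ± 132 TPM with western diet against 103 ± 24.3 TPM in control (limma adjusted p = 0.0744). The p53 and senescence list did not pass (camera adjusted p = 0.114), nor did apoptosis (0.114), antioxidant and NRF2 targets (0.179) or insulin signalling (0.133).

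The clock genes were weighed against a sex difference and a different collection time. Without western diet replicate 4, 4 clock genes were called (Hlf, Tef, Per3 and Arntl), and that library, which has Y-linked transcripts like the controls, lay beyond all controls in the called direction for 100% of them. This is 1 library, so a sex difference stays open. Of 19 clock genes, the 18 tested and Npas2, which was too low to be tested, the 6 in the arm of Arntl, which also holds Npas2, Clock, Cry1 and Nfil3, all had the higher mean with western diet, and of the other 13 genes 11 had the lower mean, the medians of the arms differing by 0.69 on the log2 scale. A shift in clock phase may give this picture, whether from the diet or from tissue taken at another time of day. The labels give no collection time, so the diet and the time of day cannot be told apart for these genes.

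Kidney transcripts were found in the western diet hearts, and a candidate explanation is traces of kidney RNA. The values of Kap, Umod, Miox and Slc34a1 were seen before the test. Kap, the most abundant of them, was at 7.15 to 72.1 TPM there, Umod was listed at 0 in western diet replicates 1 and 3 and at 0.405 and 1.34 TPM in replicates 2 and 4, and Miox and Slc34a1, listed at 0 in all controls, were at 0.601 to 2.73 and 0.259 to 2.86 TPM. Of 39 kidney markers not looked at before and with a control mean under 0.5 TPM, 36 (92.3%) had the higher mean with western diet, and their sum was highest in western diet replicate 4 (19.6 TPM, against 5.98 to 7.12 in the other western diet libraries and 1.83 to 2.54 in the controls). Western diet replicate 4 is also the only western diet library with Y-linked transcripts. A sex difference and the amount of kidney RNA therefore cannot be told apart in its higher sum. A general rise of low transcripts of other organs was weighed as the whole cause, with Napsa taken out of the lung list. The kidney sum was at least 2.72 times the control mean in each western diet library. The sums of liver markers, of lung epithelial markers other than Napsa and of all 9012 genes at that level reached at most 1.65 times theirs. This argues against a general rise in those sets as the whole cause. With Napsa kept, the lung list was at 5.27 to 6.40 times its control mean, so the comparison rests on taking that gene out. By direction alone the sets were closer: 7 of 9 lung markers (77.8%), 56.7% of the 9012 genes and 0 of 6 liver markers had the higher mean with western diet. All 4 western diet libraries lay above all controls for 13 of the 39 kidney markers, 199 of the 9012 genes and 0 of these 9 lung and 6 liver markers. Kidney RNA as the source of Napsa, which kidney also expresses, stays open too. Napsa varied 1.28-fold over the 4 western diet libraries and the kidney sum 3.28-fold, but without western diet replicate 4 the kidney sum varied 1.19-fold and Napsa 1.28-fold. The 9 other low members of the lung epithelial list summed to 0.415 ± 0.165 TPM with western diet and 0.351 ± 0.0980 TPM in control (exact permutation p = 0.543).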
